A study of Ovis aries with 2 samples.

How the data were processed

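The series measured single-cell gene expression in the anterior pituitary of Hu sheep at 3 and 6 months of age, with 1 library per age. Per the labels' protocols, the anterior lobe was separated by morphology, digested with type IV collagenase, passed through a 40 µm strainer and freed of red blood cells. Cells were then partitioned on a Chromium droplet system, and the cDNA was sequenced as DNA nanoballs. The number and sex of the animals behind each library are not given in the sources used here. Each library therefore counted as 1 sample of its age, and age and library could not be separated.

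The authors deposited raw UMI counts per gene and barcode for each library, without normalization. Reads were counted with Cell Ranger 5.0.0 per the submitters' processing notes, while the matrix headers name version 5.0.1. The genome build and annotation behind the counts are not given in the sources used here. The feature and barcode lists the authors deposited beside the counts hold other, non-numeric entries: gene symbols with NCBI Gene identifiers, and cell barcodes. Of the 23141 listed genes, 22726 identifiers (98.2%) matched a reference gene table of the ARS-UI_Ramb_v3.0 assembly. That table was used for names only. It replaced 439 placeholder symbols, 6561 genes kept a placeholder, and 19381 genes had a count. The 13 mitochondrially encoded genes had 0 counts in both libraries, so the limit of 20% mitochondrial UMIs set beforehand had no effect and the list of those genes gave no result.

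The 3-month library held 18961 barcodes and 142479651 UMIs, with a median of 4361 UMIs and 1763 genes per barcode. The 6-month library held 15031 barcodes and 175239612 UMIs, with medians of 7434 UMIs and 2381 genes. The lowest total was 500 UMIs in both. Barcodes with at least 500 genes and 1000 UMIs were kept, 16368 and 13253 of them. Doublets were marked per library with Scrublet, as built into scanpy, at its automatic threshold. They made up 964 barcodes (5.89%) at 3 months and 656 (4.95%) at 6 months and were removed. An assumed rate of 0.8% per 1000 barcodes would give 13.1% and 10.6%, so undetected doublets probably remained. Their number was not measured. This left 15404 and 12597 cells.

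Counts were scaled to 10000 per cell and log-transformed. The 3000 most variable genes, without hormone, mitochondrial and ribosomal protein genes, were scaled, clipped at 10 and reduced to 30 principal components. A graph of 15 nearest neighbours was divided by the Leiden method at resolution 1.0 with 5 iterations and seed 1, without integration, which gave 38 clusters. Clusters were named from 104 markers of 17 cell classes, of which 95 were in the feature table. A marker supported a class when it was 1.5-fold higher in the cluster and present in at least 10% of its cells. A name needed at least 3 supporting markers, a mean marker log2 fold of at least 0.7, and no other class with more markers, also among the 10 leading genes found in at least 20% of cells. The markers were chosen before the data were examined. The scoring rule was written after the clusters had been seen. It was the last of 4 versions, picked after comparing the names they gave across settings. Under some settings clusters nearest to lactotrophs or thyrotrophs still stayed unnamed, and the other 3 versions were run as alternatives.

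Counts of a class were summed per library and compared as CPM on edgeR TMM effective library sizes. CPM of single clusters, of all cells and of IFNG, and ratios of class to all-cell CPM, were taken on UMI totals without TMM. With 1 library per age no test was possible, and no p-value or standard error was computed. Shares have exact Clopper-Pearson intervals and ratios of summed counts have exact conditional binomial intervals, all at 95%. These intervals cover counting error only and say nothing of variation between animals or preparations. For ratios they treat all UMIs of a class as independent, so variation between its cells is left out too. A gene at a count of 0 was set against a floor of 3 counts over the class, which makes the fold a lower bound. A gene was counted as 2-fold apart when it had at least 100 summed counts in the class, differed at least 2-fold, and reached 0.5 of the all-cell CPM of the library in which it was higher. The last condition is meant to keep out genes that free RNA could bring. It was not applied to the counts of list members, which may include such genes. Ratios are log2 of the 6-month over the 3-month library unless stated otherwise.

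The genes named follow a rule that was likewise set beforehand. They are the hormone and receptor genes of each class, then up to 12 higher and 12 lower genes per class in order of the interval bound nearer to 0. The text mostly takes them from the top of that order. For lactotroph-like cells it departs from it, as CHGA is given before GAL, whose bound lies farther from 0. Some results on single genes are not reported here. Of 22 gene lists fixed beforehand, 20 were compared. The list of mitochondrially encoded genes had 0 counts and the sex-linked list had 0 members in the feature table. List members needed 20 summed counts, and up to 4 members at least 2-fold apart are named in the same order. The median log2 ratio of a list is given with its percentile among 10000 random lists of the same size drawn from 10 expression bins, as a description of these libraries. Classes other than the hormone-producing ones were compared from 100 cells per library. Detection shares were taken after thinning each cell to 2000 UMIs and leaving out shallower cells.

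The comparison was tested on simulated counts drawn from the real gene means and library sizes with 200 changed genes. For the gonadotroph comparison of 9537 genes, 100 of 100 genes changed 4-fold and 99 of 99 changed 2.83-fold were found, and 2 of 9338 unchanged genes passed. The intervals held the true ratio for 95.4% of genes. Over 6 simulated classes, 5 of 120 unchanged lists (4.2%) fell in the outer 5% of random lists. Genes were drawn independently of each other and without variation between cells, so a share near 5% was built in. The simulation does not show how often real lists, whose genes can vary together, reach extreme percentiles.

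Alternatives were a looser filter (200 genes and 500 UMIs), a stricter filter (1000 genes and 2000 UMIs), doublets kept, Leiden resolutions 0.5 and 2.0, hormone genes kept among the variable genes, and genes scaled within each library. Expression was also scaled by library totals, by median-of-ratios size factors and by totals without hormone genes, taken as the mean of per-cell CPM, or corrected by subtracting the library's all-cell profile at a free RNA share estimated from hormone genes in endothelial and immune cells. That estimate was 11.4% at 3 months and 27.9% at 6 months. It pools unlike classes: at 6 months PRL took 13.4% of UMIs in macrophage-like and 12.6% in B or plasma-like cells. In endothelial-like and T or NK-like cells PRL took 4.22% and 3.82%, against 34.8% over all cells. The pooled 6-month share may therefore be too high for other classes, which bears on every value with free RNA subtracted. Minimum counts of 20 and 300 were tried for the counts of genes. Alternatives added after seeing the data were the 3 other naming rules, gonadotrophs without cluster 31, lactotrophs of cluster 7 alone, and shares among hormone-producing cells. List members were also compared without cluster 31, in cluster 7 alone and with free RNA subtracted. The tools were Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scanpy 1.11.5, scikit-learn 1.9.0, leidenalg 0.10.2, matplotlib 3.10.9, R 4.3.3 and edgeR 4.0.16.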

Results

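Single-cell expression profiles were compared between dissociated anterior pituitaries of Hu sheep aged 3 and 6 months, a design aimed at the gland around puberty. Each age had 1 library. After filtering, 15404 cells at 3 months and 12597 cells at 6 months were analysed, from libraries of 142479651 and 175239612 UMIs. Since neither age had a second library, the differences have no replicate check, no test was run, and every difference is one between these libraries. Hormone transcripts in endothelial and immune cells, which should lack them, moved in different directions. PRL made up 2.66% of UMIs in those cells at 3 months and 9.82% at 6 months, against 21.7% and 34.8% over all cells. GH made up 0.270% and 0.285% (2.98% and 0.829% over all cells), CGA 0.140% and 0.0677% (2.08% and 0.681%), and LHB 0.0237% and 0.00941% (0.331% and 0.108%).

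The 6-month library held a larger share of lactotroph-like cells and smaller shares of the other main hormone-producing classes. Lactotroph-like cells, which make prolactin, were 17.2% (95% interval 16.6 to 17.8) of kept cells at 3 months (2648 cells) and 43.4% (42.5 to 44.3) at 6 months (5465 cells). Gonadotroph-like cells, the source of LH and FSH, were 7.61% (7.2 to 8.05; 1173 cells) and 2.06% (1.82 to 2.33; 260 cells). Somatotroph-like cells, which make growth hormone, were 8.40% (1294 cells) and 3.92% (494 cells). Corticotroph-like cells were 1.35% (208 cells) and 0.056% (7 cells). Thyrotroph-like cells were rare in both libraries, with 26 and 46 cells. Among the cells of named hormone-producing classes alone, gonadotroph-like cells made up 21.9% and 4.15%, somatotroph-like cells 24.2% and 7.88%, and lactotroph-like cells 49.5% and 87.1%.

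Other classes also differed in share. Stem or folliculostellate-like cells were 34.0% at 3 months and 18.9% at 6 months, and endothelial-like cells 12.2% and 3.42%. T or NK-like cells were 0.721% (111 cells) and 8.14% (1025 cells), and B or plasma-like cells 0.084% and 0.619%. Macrophage-like cells were 8.55% and 10.5%, a difference of 1.94 points that was 5.48 under the looser filter, 3.09 at resolution 0.5 and 5.03 under the third naming rule, but 1.24 at resolution 2.0. T or NK-like cells differed by 7.42 points, or 4.27 under the stricter filter. Fibroblast-like cells were 0.928% and 0.230%, and 8.86% and 8.45% of cells stayed unnamed.

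These shares are shares of recovered cells and depend on dissociation, filtering and naming. Of the 38 clusters, 11 held at least 90% cells of the 3-month library and 10 at least 90% cells of the 6-month library, so some may be libraries and not cell types. Different clusters were the largest of several classes in each library: 11 (75.1%) and 31 (55.0%) for gonadotroph-like cells, 8 (58.3%) and 2 (48.7%) for lactotroph-like cells, 1 (56.5%) and 9 (48.7%) for stem-like cells, 4 (99.6%) and 25 (42.5%) for endothelial-like cells, and 14 (47.8%) and 10 (76.5%) for macrophage-like cells. Cluster 6 held most somatotroph-like cells in both (93.6% and 99.4%), and cluster 13 most T or NK-like cells (62.2% and 66.2%). The naming rule, set after the clusters were seen, kept out 3 clusters nearest to stem cells (5.54% of cells at 3 months, 2.89% at 6 months), 1 nearest to lactotrophs (0.039% and 1.36%), 1 nearest to macrophages (0.253% and 1.85%), 1 nearest to B cells (0.0195% and 0.357%), and 2 with under 3 markers of any class (3.01% and 2.00%). The lactotroph difference of 26.2 points was 11.04 under the looser filter, where a large cluster of such cells stayed unnamed.

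**Figure D1:**
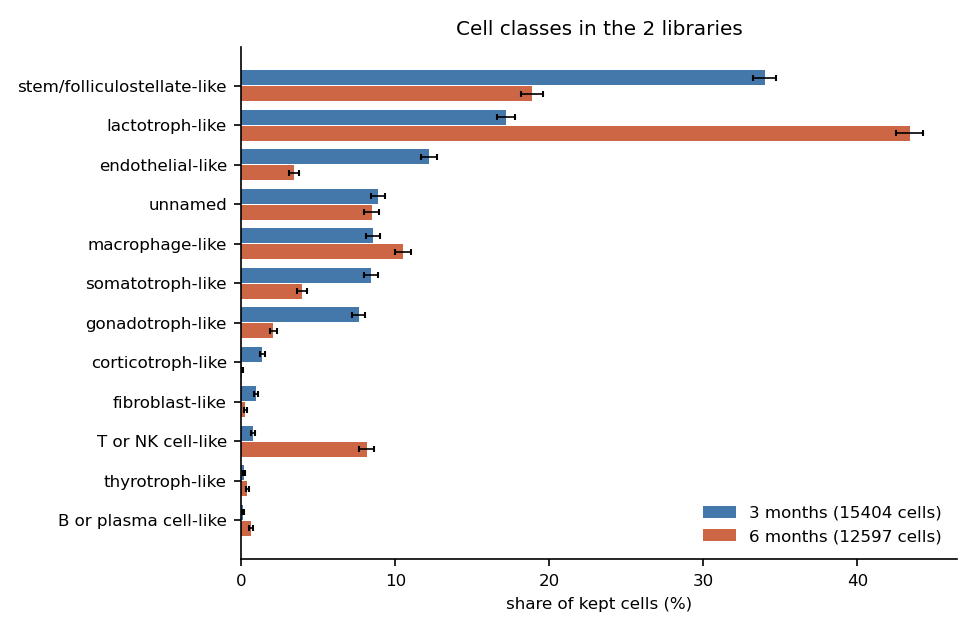
Share of kept cells (percent, horizontal axis) for each named class (vertical axis) in the 3-month and 6-month libraries, 1 library per age, with exact 95% intervals for counting error as error bars. Lactotroph-like cells made up 17.2% and 43.4% of the libraries, and gonadotroph-like cells 7.61% and 2.06%.

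In gonadotroph-like cells, the gonadotropin subunit genes differed little and in opposite directions. LHB (NCBI Gene 443395), the LH beta subunit, had 27873 CPM at 3 months and 35720 CPM at 6 months, a log2 ratio of 0.36 (0.35 to 0.37). FSHB (443387), the FSH beta subunit, had 1608 and 1295 CPM (−0.31, −0.35 to −0.27). CGA (443538), the shared alpha subunit, was at 0.40, and GNRHR (443413), the GnRH receptor, at 0.08 (350.5 and 371.5 CPM). LHB took 2.94% and 3.38% of the UMIs of the class, CGA 17.4% and 20.6%, and FSHB 0.170% and 0.123%, against 0.00096% and 0.00013% FSHB in endothelial and immune cells. Median depths were 10954 and 18395 UMIs per cell.

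The FSHB difference depended on which gonadotroph-like cells were taken. CPM of single clusters were taken on UMI totals without TMM, unlike the class values above. Cluster 31 held 143 cells of the 6-month library and 2 of the 3-month library. Its 6-month cells had a median of 24044 UMIs, 29948 CPM of LHB and 240347 CPM of CGA but only 199.9 CPM of FSHB. In cluster 11, FSHB was at 1716 CPM in 881 cells at 3 months and 3993 CPM in 84 cells at 6 months, and LHB at 29283 and 43863 CPM. In the shallow cluster 22, FSHB was at 1298 CPM in 290 cells and 280.3 CPM in 33 cells. Without cluster 31, a comparison added after seeing the data, the log2 ratio of FSHB was 1.10, that of LHB 0.54, that of CGA −0.48 and that of GNRHR −0.37. FSHB was also at 0.03 as the mean of per-cell CPM, and GNRHR at −0.01 under the stricter filter and −0.07 on library totals.

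After thinning to 2000 UMIs, FSHB was detected in 50.3% (47.2 to 53.5) of 1011 gonadotroph-like cells at 3 months and in 31.3% (25.5 to 37.5) of 243 at 6 months, out of 1173 and 260 cells, the shallower ones being left out. The share in endothelial-like cells, with median depths of 2750.0 and 3286 UMIs, was 1.02% and 0.284%, in 1373 and 352 cells deep enough of 1872 and 431. GNRHR was detected in 45.0% and 42.8% of gonadotroph-like cells, and LHB in 99.1% and 99.6%, against 25.8% and 8.52% for LHB in endothelial-like cells. Without thinning, FSHB was detected in 59.3% and 41.9% of gonadotroph-like cells and GNRHR in 76.2% and 79.6%. The direction for FSHB differed between clusters: without thinning it was detected in 62.5% and 75.0% of cells in cluster 11, in 49.3% and 21.2% in cluster 22, and in 27.3% of the 6-month cells of cluster 31.

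**Figure D2:**
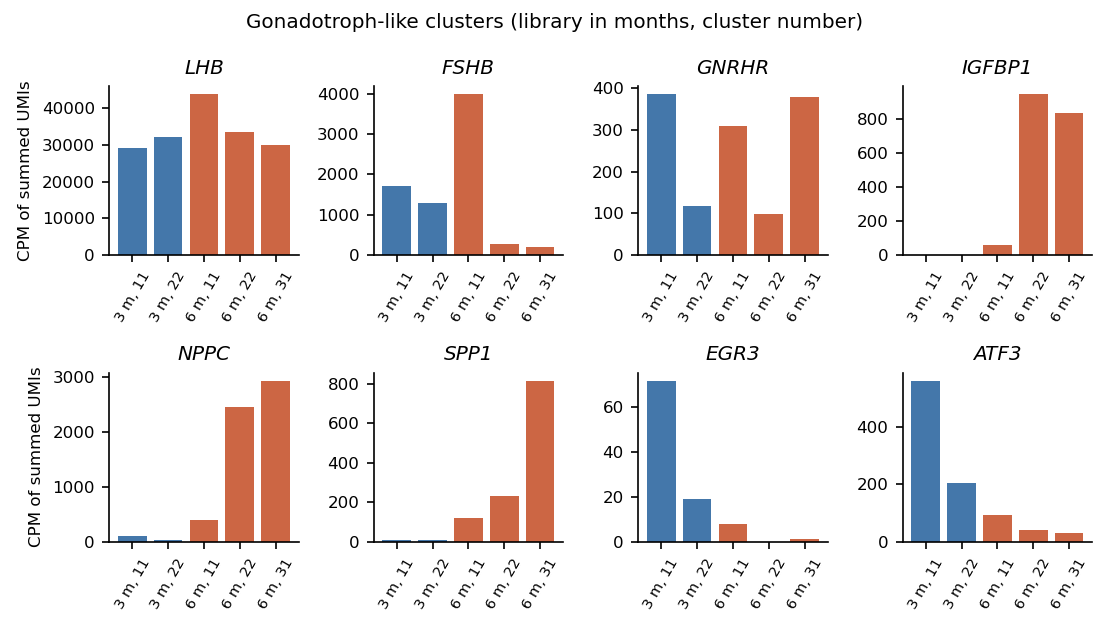
CPM of summed UMIs (vertical axes) of LHB, FSHB, GNRHR, IGFBP1, NPPC, SPP1, EGR3 and ATF3, genes chosen after their values were seen, in the gonadotroph-like clusters 11 and 22 of both libraries and cluster 31 of the 6-month library; each bar is 1 cluster in 1 library. FSHB was at 3993 CPM in cluster 11 and 199.9 CPM in cluster 31 of the 6-month library, while IGFBP1 was at 57.8 and 837 CPM.

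Among genes higher in gonadotroph-like cells of the 6-month library, IGFBP1, CALCB, CHRDL2 and SPP1 stood first. IGFBP1, an insulin-like growth factor binding protein, had 1 UMI at 3 months and 3028 at 6 months, a log2 ratio of 13.20 (10.72 to 18.50). CALCB, a calcitonin gene-related peptide, had 0 and 291 UMIs and was at least 302-fold higher, and CHRDL2 had 0 and 166, a log2 ratio of at least 7.43. SPP1, which encodes osteopontin, was at 6.82 (6.5 to 7.15). MUSK (8.71, 6.21 to 14.03), CALCA (7.87, 5.99 to 10.92) and GABRA3 (7.84, 5.96 to 10.90) rested on 1 or 2 UMIs at 3 months. Next came KLHL41 (5.18), NPPC, the precursor of C-type natriuretic peptide (4.61, 4.53 to 4.69), TAC3, which encodes neurokinin B (5.25), PGF (4.99) and DIO2, the deiodinase that activates thyroid hormone (4.41, 4.17 to 4.66).

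EGR4, H1-2 and EGR3 led the lower genes, of which EGR3, EGR4, ATF3 and IER2 are induced by stimuli. EGR4 had 1592 UMIs at 3 months and 14 at 6 months (−5.19, −6.07 to −4.44), and EGR3 was at −4.40 (−5.28 to −3.64). The linker histone gene H1-2 was at −4.51, BST1 at −3.80, LRRC17 at −4.52 and ATF3 at −3.38 (513.7 and 49.2 CPM). C20H6orf141 had 100 and 0 UMIs, a log2 ratio of −3.42 or lower. NR1D1, a clock repressor, rested on 1 UMI at 6 months (−5.35, −10.67 to −2.85). CDH13 was at −3.35, GSG1L at −3.40, IER2 at −2.81 and MSMB, which encodes a microseminoprotein, at −2.61 (1178 and 193 CPM).

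In all, 335 genes were at least 2-fold higher and 474 at least 2-fold lower, of 9608 measured. The split was 226 and 691 on library totals and 297 and 664 as the mean of per-cell CPM. Without cluster 31, 397 genes were 2-fold apart, 83 higher and 314 lower, and these need not be among the genes counted over all cells. The log2 ratios of the higher genes named above were then 10.93 for IGFBP1, at least 5.09 for CALCB, at least 5.33 for CHRDL2 and 4.41 for SPP1. They were 5.53 for MUSK (1 and 5 UMIs, interval 2.37 to 11.10), 2.00 for KLHL41, 2.54 for NPPC, 4.45 for TAC3, 6.39 for PGF and 2.11 for DIO2. CALCA (2 and 1 UMIs) and GABRA3 (2 and 2) then had too few counts for a ratio. Those of the lower genes were −5.51 for H1-2 (846 and 2 UMIs; −8.56 to −3.66), −3.31 for EGR3, −2.86 for BST1, −2.64 for ATF3, −2.38 for CDH13, −3.78 for NR1D1 (127 and 1 UMIs; −9.09 to −1.27) and −1.85 or lower for C20H6orf141. Subtracting free RNA moved SPP1 to at least 11.83, DIO2 to 7.27, EGR4 to −6.08, EGR3 to −6.23 or lower, H1-2 to −6.69, ATF3 to −8.99 or lower and IER2 to −3.99. HSPA1A, H1-2 and GH, named here and for other classes, have near-identical relatives, from which their counts could not be separated.

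**Figure D3:**
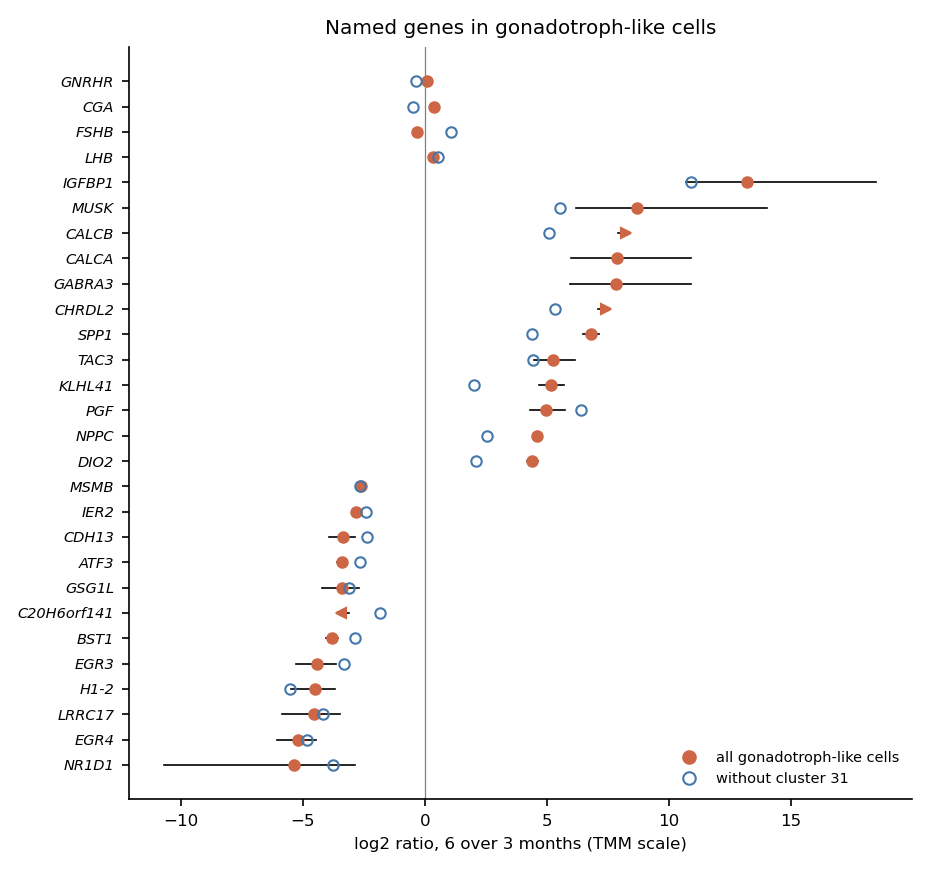
Log2 ratio of the 6-month over the 3-month library (horizontal axis, TMM-scaled summed UMIs) for 28 genes (vertical axis), the 24 named by rank and 4 hormone and receptor genes, with 95% counting intervals; filled circles are all gonadotroph-like cells, open circles those outside cluster 31, and triangles bounds against a floor of 3 counts. IGFBP1 was at 13.20 with and 10.93 without cluster 31, and FSHB at −0.31 with and 1.10 without it.

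Immediate early and dissociation response genes formed the list that stood lowest in gonadotroph-like cells. Of 21 measured, 15 were at least 2-fold lower and 1 higher, with a median of −1.61 (percentile 0 among random lists), or −0.90 without cluster 31 and −2.36 with free RNA subtracted. Examples were EGR3 (−4.40), ATF3 (−3.38), IER2 (−2.81) and ZFP36 (−2.77), and IER3 was higher (1.03, or −0.06 without cluster 31). The list of gonadotroph regulation and GnRH response, which shares ATF3, NR4A1 (−1.91), FOS (−1.75) and EGR1 (−1.61) with it, had 7 of 25 lower and 0 higher (median −0.57, percentile 0). Without cluster 31, FOS was at −0.72 and EGR1 at −0.82, both under 2-fold. Interferon response and MHC genes had 8 of 18 lower and 0 higher (median −0.62, percentile 0.04), among them IFI6 (−3.34), ISG15 (−2.36) and IFIT1 (−2.95), or −2.63, −1.80 and −1.60 without cluster 31. The median of this list was −2.47 with free RNA subtracted.

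Lists that describe the endocrine state were mixed. Nuclear hormone receptors had a median of −0.74 (percentile 0.31), or −1.39 with free RNA subtracted, with 3 of 13 lower and 2 higher: NR4A1 and ESR1, the estrogen receptor alpha (−1.23), against NR3C1 (1.33) and PGR (1.12). Without cluster 31 none of these but NR4A1 (−1.40) was 2-fold apart: ESR1 was at −0.38, NR3C1 at 0.72 and PGR at −0.27. Prohormone processing and granule genes were at −0.03 (percentile 36.3), but 5 of 22 were higher, led by the convertase gene PCSK1 (3.27), RESP18 (2.26) and VGF (2.19), and RAB3B was lower (−1.74). Without cluster 31, PCSK1 was at 1.58, RESP18 at 3.35 and VGF at 0.82. Puberty-associated genes were at 0.08 (percentile 73.2), with TAC3 and POU1F1 (2.07), a gene of other classes, higher and ESR1 among 2 of 9 lower. The median of this list turned to −0.34 without cluster 31, −0.13 under the stricter filter, −0.10 as the mean of per-cell CPM and −0.07 on library totals. Hypophysiotropic receptors were at 0.79 (percentile 99.9), where DRD2 (2.44), a lactotroph gene, was 1 of 2 higher members of 7. Activin, inhibin and BMP signalling genes were at −0.00 (percentile 63.0), with 3 of 25 higher and 2 lower, including TGFB2 (3.04, or 1.00 without cluster 31), BMP2 (−1.65) and ACVR1 (1.47). Lineage transcription factors were at −0.32 (percentile 2.03) and at 0.01 without cluster 31, with POU1F1 among 2 of 18 higher and SOX9 (−1.03, or −2.003 without cluster 31) among 3 lower. Unfolded protein response genes were at 0.37 (percentile 99.8), with EDEM1 (1.61) and CRELD2 (1.06, or 0.72 without cluster 31) higher and 0 of 20 lower.

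The other lists of this class differed less or had few members apart. Hormone genes were at −0.31 (percentile 5.94), with PRL (2.13) higher and POMC (−2.95) and TSHB (−2.03) lower, all genes of other classes, and the median was 0.35 with genes scaled within each library, 0.65 with free RNA subtracted and 0.03 without cluster 31 and as the mean of per-cell CPM. Cell cycle genes were at −0.61 (percentile 7.36; HMGB2 at −1.74, or −1.13 without cluster 31), and extracellular matrix genes at −0.44 (percentile 7.18; THBS1 at 4.51, or 2.68 without cluster 31, COL1A2 at −1.502), or −1.03 under the looser filter and −1.14 as the mean of per-cell CPM. Notch, Wnt and Hippo genes were at −0.37 (percentile 6.66; DLL1 at 1.66, or −0.30 without cluster 31, CCN1 at −1.34) and thyroid hormone and IGF axis genes at −0.27 (percentile 4.19; DIO2 at 4.41). Heat shock genes were at −0.21 (percentile 5.18), with HSPA1A at 1.91, or 2.96 without cluster 31, and DNAJB4 at −1.16. Cholesterol synthesis genes were at 0.13 (percentile 85.3; HMGCS1 at −1.11, or −0.84 without cluster 31) and neuronal excitability genes at 0.07 (percentile 73.0; GRIA2 at −2.14). Oxidative phosphorylation genes (−0.21, percentile 1.02) and cytosolic ribosomal proteins (−0.01, percentile 36.8) had 0 members 2-fold apart. Other medians near 0 changed sign as well: without cluster 31 the activin, inhibin and BMP list was at 0.14, ribosomal proteins at 0.03 and neuronal excitability at −0.04, on library totals cholesterol synthesis was at −0.02 and neuronal excitability at −0.09, and with doublets kept granule genes were at 0.02. Among the members named for this class, POU1F1, DRD2, PRL, POMC, TSHB, CCN1, COL1A2, EDEM1, IER3, IFI6, IFIT1, THBS1 and ZFP36 stood below 0.5 of the all-cell CPM, so that free RNA could bring them. After its subtraction 0 counts of POU1F1, DRD2, PRL, POMC and TSHB were left in either library. The amount subtracted was at least all they had, for PRL 1.45% and 5.69% of the UMIs of the class. These zeros were thus set by the estimated free RNA share and do not show where the counts came from.

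**Figure D4:**
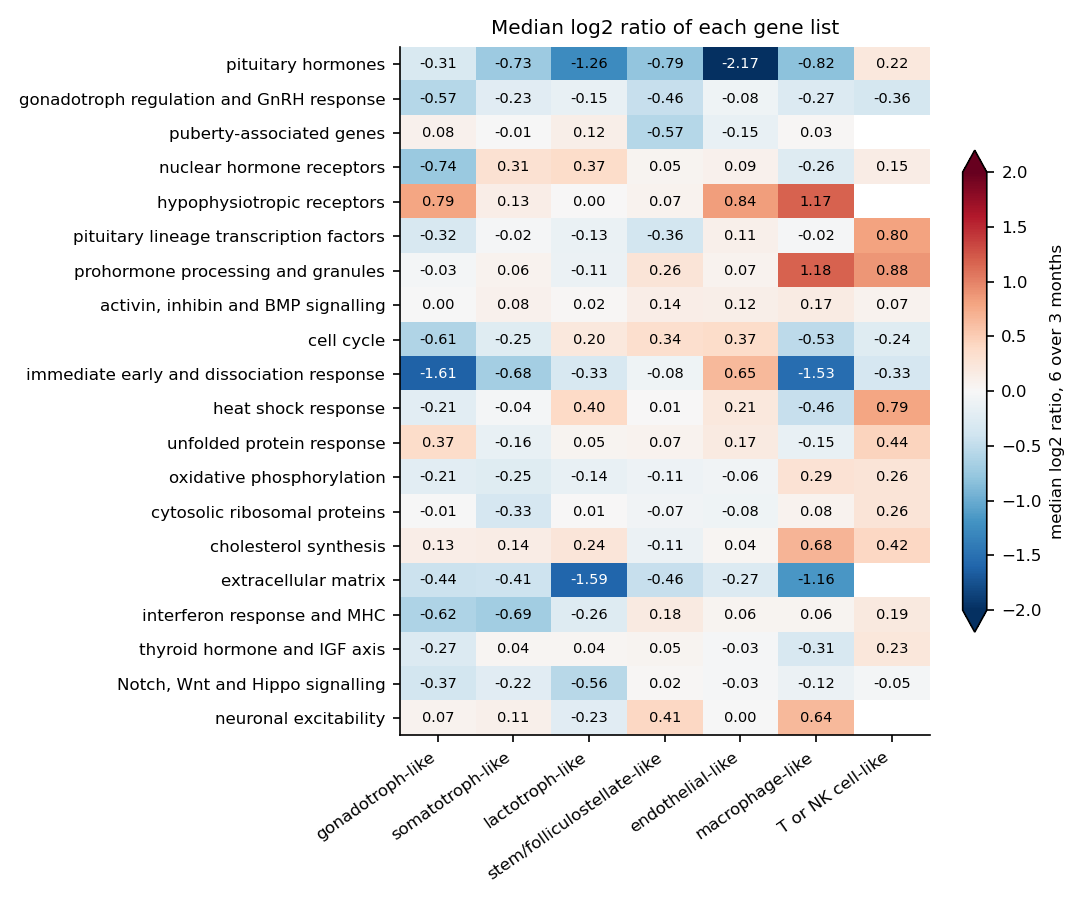
Median log2 ratio of the 6-month over the 3-month library (colour, capped at −2 and 2) for 20 gene lists (vertical axis) in 7 classes (horizontal axis). Immediate early genes had medians of −1.61 in gonadotroph-like, −1.53 in macrophage-like and 0.65 in endothelial-like cells.

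Somatotroph-like cells differed least by the count of genes among the main endocrine classes. GH (443329) had 363127 CPM at 3 months and 261080.1 CPM at 6 months (−0.48, −0.48 to −0.47), or 33.6% and 28.2% of the UMIs of the class, against 0.270% and 0.285% in endothelial and immune cells. GHRHR (443511), the receptor of growth hormone-releasing hormone, was at −0.12 (−0.19 to −0.05) and changed sign under several scalings, with 0.11 on library totals and 0.27 as the mean of per-cell CPM. The heat shock gene HSPA1A (1.99), SENP6 (1.66), ENPEP (1.54) and LYZL6 (1.61) led the 33 higher genes. The 100 lower genes, of 8671 measured, were led by the interferon-induced ISG15 (−3.37, −3.60 to −3.15), the chemokine CXCL14 (−3.12), GADD45G (−2.74) and DEFB1 (102 and 3 UMIs; −3.89, −6.19 to −2.30).

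Interferon response and MHC genes in this class had a median of −0.69 (percentile 0), with 7 of 16 lower and 4 higher. IFI6 (−3.82), ISG15, IFIT1 (−2.91) and MX2 (−2.91) were lower. Immediate early genes were at −0.68 (percentile 0), with 6 of 21 lower, among them ATF3 (−2.61), FOS (−1.35), IER2 (−1.48) and ZFP36 (−1.45). With free RNA subtracted these medians were −2.22 and −2.79, ISG15 was at −4.66, and 201 genes were 2-fold apart. The split of 33 higher and 100 lower genes depended on scaling: it was 114 and 64 on library totals, 89 and 71 on totals without hormone genes, and 201 and 92 as the mean of per-cell CPM.

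Lactotroph-like cells of the 6-month library had lower CHGA and GAL. CHGA, which encodes the granule protein chromogranin A, was at 1196 CPM at 3 months and 53.1 CPM at 6 months (−4.49, −4.53 to −4.45), and GAL, which encodes the neuropeptide galanin, at 385.8 and 4.25 CPM (−6.51, −6.65 to −6.37). PRL (443317) had 569995 and 496242 CPM (−0.20, −0.20 to −0.20), or 54.9% and 51.6% of the UMIs of the class. DRD2, the dopamine receptor, was at 0.21 and TRHR at 0.05 (−0.03 to 0.13). RGS5 (−8.24), the protease gene TPSB2 (−7.31), TBX19 (312 and 4 UMIs, −7.47) and IGFBP6 (−6.26) were among the leading lower genes. TBX19 is a corticotroph marker and was also a leading gene of the corticotroph-like cluster 24 (208 and 7 cells). Whether such cells account for its ratio was not tested. HSPA1A (3.21, 3.16 to 3.25), HRH3 (2.84), RLN3, which encodes relaxin 3 (2.76), SERTAD3 (2.24) and BDNF (2.35) led the higher genes.

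Extracellular matrix genes stood apart in this class, with 14 of 17 lower, 0 higher and a median of −1.59 (percentile 0), led by DCN (−5.40), SPARC (−2.17), TIMP1 (−1.52) and COL5A2 (−1.45). DCN and RGS5 were also among the 10 leading genes of the fibroblast-like cluster 28, whose class made up 0.928% and 0.230% of cells, and SPARC and TIMP1 stood below 0.5 of the all-cell CPM. Heat shock genes were at 0.40 (percentile 100), with HSPA1A and HSPB1 (1.00) the 2 higher members of 12. Granule genes were at −0.11 (percentile 6.12), with VGF (−2.05), RESP18 (−2.08) and CHGA among 4 of 22 lower and SYT1 (2.09) higher. The receptor genes SSTR2 (−3.56) and AGTR1 (−2.26) and, among puberty-associated genes, LEPR, the leptin receptor (−2.91), were lower too. In all, 205 genes were higher and 295 lower of 11973, against 275 and 257 on library totals and 257 and 146 under the third naming rule.

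The clusters behind the lactotroph-like class differed between libraries, and PRL changed sign with them. It was at 0.42 in cluster 7 alone, a comparison added after seeing the data, at 0.16 under the third naming rule and at 0.04 under the looser filter. In cluster 7, CHGA was at −3.62, IGFBP6 at −3.52, TPSB2 at −3.80, DCN at −2.75 and TBX19 at −5.39, and, among list members, TIMP1 was at −0.59, SPARC at −2.87, VGF at −0.64, AGTR1 at −1.65 and SYT1 at 1.48. There RESP18 turned to 2.43 (3 and 68 UMIs; 0.83 to 4.75) and SSTR2 was at −1.07 (2 and 4 UMIs; −3.87 to 2.40). In that cluster 197 genes were higher and 123 lower. With free RNA subtracted, RGS5 was at −10.68 or lower, IGFBP6 at −11.76 or lower, CHGA at −5.28 and the matrix list at −3.90. The gap in GAL differed widely between clusters: it was at 455 and 285 CPM in cluster 8 (1545 and 50 cells), 451 and 0 CPM in cluster 21 (301 and 32 cells), 18.4 and 0.173 CPM in cluster 7, 4.32 and 0.2999 CPM in cluster 2, and 2.10 and 1.60 CPM in cluster 5. Clusters 8 and 21, which held nearly all GAL UMIs at 3 months (16425 and 933), had few cells at 6 months. Over the class GAL was at −5.90 under the looser filter and −7.22 as the mean of per-cell CPM.

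Corticotroph-like and thyrotroph-like cells were too few at 6 or 3 months for more than their leading values. POMC, the ACTH precursor gene, was at 0.03 (−0.05 to 0.11), from 208 and 7 cells, or at 0.69 on library totals, 0.78 on totals without hormone genes and 1.25 as the mean of per-cell CPM. CRHR1 had 109 and 0 UMIs, a difference not detectable at this depth. NPPC was lower (1014 and 3 UMIs; −3.30, −5.58 to −1.75), or −1.73 under the looser filter, −2.61 under the stricter filter, −2.64 on library totals and −2.55 on totals without hormone genes. Of 1272 genes, 7 were higher and 398 lower, or 97 and 206 on library totals. The corticotroph-like class held 781598 UMIs at 3 months and 14381 at 6 months and was not among the simulated classes. How many of these genes differ only through low counts was not measured. In thyrotroph-like cells TSHB, the TSH beta subunit gene, was at −0.97 (−1.02 to −0.92), or −0.14 as the mean of per-cell CPM, and CGA at −0.45. CALCA had 0 and 108 UMIs in this class (a log2 ratio of at least 4.58), and PCP4 was at 2.63 (1.94 as the mean of per-cell CPM). Of 449 genes, 10 were higher and 0 lower, or 7 and 3 on library totals.

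The chemokine genes CXCL9, CXCL10 or CXCL11, which interferon induces, were among the 4 leading higher genes of stem or folliculostellate-like, endothelial-like and macrophage-like cells. In stem-like cells, DMBT1 had 0 and 174 UMIs (a log2 ratio of at least 6.19), CXCL10 was at 5.74 (5.45 to 6.05), CXCL1 at 6.02 and CXCL11 at 5.53. In endothelial-like cells, CXCL9 was at 3.88 CPM at 3 months and 3171 CPM at 6 months (9.67, 9.11 to 10.30), CXCL10 at 7.52, IDO1, which encodes a tryptophan-degrading enzyme, at 7.22, IL32 at 6.22 and the MHC class II chaperone gene CD74 at 5.05. In macrophage-like cells, CXCL9 was at 5.03 (4.86 to 5.20), PLA2G2D at 5.09, CXCL11 at 4.32 and IDO1 at 4.67. As the mean of per-cell CPM the stem-like values of CXCL10 and CXCL11 were 4.96 and 4.61. Free RNA subtraction gave 7.24 for CXCL10 and at least 7.50 for CXCL1 in stem-like cells and 7.74 for CD74 in endothelial-like cells. Under the looser filter, CXCL9 and IDO1 in macrophage-like cells were at 5.90 and 6.33.

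Interferon-related genes went both ways in these classes. In stem-like cells IRF1 (2.76), CD74 (2.42) and TAP1 (1.80) were among 6 of 18 higher and IFI6 (−2.18) and ISG15 (−2.07) among 5 lower (median 0.18, or −0.15 with free RNA subtracted). In endothelial-like cells CD74, ISG20 (5.23) and IRF1 (2.37) were among 4 higher and IFI6 (−3.001) among 6 lower (median 0.06, or −0.26 as the mean of per-cell CPM). CDH15 (99 and 1 UMIs; −6.29, −11.61 to −3.78) and the Notch target HES5 (−3.37, −3.58 to −3.17) led the lower genes of stem-like cells. CYP1A1 (279 and 0 UMIs; −4.77 or lower), ABI3BP (407 and 3 UMIs; −5.32, −7.60 to −3.76, and −3.24 with doublets kept) and CD55 (196 and 2 UMIs; −4.85, −7.90 to −2.97) led those of endothelial-like cells.

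In macrophage-like cells, CCL24 (−3.72), STEAP4 (−3.82), CLEC5A (−3.70) and NFKBIZ (−3.14) were lower, with CLEC5A at −1.56 and NFKBIZ at −2.40 under the looser filter. Their immediate early genes were at −1.53 (percentile 0; 14 of 21 lower), while those of endothelial-like cells were at 0.65 (percentile 100; 6 of 21 higher), those of stem-like cells at −0.08 (0.04 as the mean of per-cell CPM and 0.09 with free RNA subtracted) and those of lactotroph-like (percentile 0.01) and T or NK-like cells (percentile 0) both at −0.33. Cholesterol synthesis genes of macrophage-like cells were at 0.68 (percentile 100, 5 of 19 higher), with SQLE (1.74), FDPS (1.47) and MSMO1 (1.08). Prohormone processing and granule genes were at 1.18 in this class (percentile 100), with 12 of 21 higher and 3 lower. PRL took 3.12% and 13.4% of its UMIs. Whether RNA of hormone-producing cells lifted the cholesterol list was not tested. In T or NK-like cells, the chemokine gene CCL1 had 0 and 3917 UMIs and was at least 144-fold higher, and TNFRSF9, an activation-induced receptor gene, was at 3.78 (2.97 as the mean of per-cell CPM). IL17A (99 and 4 UMIs; −7.81, −9.71 to −6.41) and CRABP1 (−6.38, and −8.40 with free RNA subtracted) led their lower genes.

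The numbers of higher and lower genes were 405 and 216 of 12488 in stem-like, 214 and 215 of 7803 in endothelial-like, 320 and 384 of 8824 in macrophage-like, and 387 and 71 of 4065 in T or NK-like cells. On totals without hormone genes the split was 580 and 232 in macrophage-like cells and 223 and 143 in T or NK-like cells, where library totals gave 209 and 163. HSPA1A was higher at 6 months in all 7 classes compared by list, from 1.48 in stem-like to 3.21 in lactotroph-like cells. Scaling by library totals shifted the median gene by −0.16 in gonadotroph-like, 0.23 in somatotroph-like, 0.11 in lactotroph-like, −0.26 in T or NK-like and 0.66 in corticotroph-like cells. Totals without hormone genes shifted it by 0.18 in somatotroph-like, 0.23 in macrophage-like, −0.22 in T or NK-like, 0.75 in corticotroph-like and −0.14 in thyrotroph-like cells. Class ratios and class CPM above are relative to TMM unless another scaling is named, while CPM of single clusters are not TMM-scaled.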

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

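All tests in this part were chosen after the result was seen, except those on cluster 31 alone, on doublets in cluster 31 and on free RNA from endothelial cells, and the bound of 1 for free RNA was set after the ratios were seen. SPP1 and the immediate early genes had opposite directions in different classes, and these differences between classes were not tested. SPP1 was higher at 6 months in gonadotroph-like (6.82) and lower in somatotroph-like cells (−1.56). Immediate early genes had a median of 0.65 in endothelial-like cells, against −1.61 in gonadotroph-like, −0.68 in somatotroph-like and −1.53 in macrophage-like cells.

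Gonadotroph-like and corticotroph-like cells formed smaller shares of the 6-month library. Dilution by the more numerous lactotrophs and immune cells would leave their number per cell of every other class alike, but for corticotroph-like cells the ratio of 6 to 3 months was 0.0882 (0.0348 to 0.187) per somatotroph and at most 0.166 per cell of the other 4 classes taken. For gonadotroph-like cells it was 0.581 (0.488 to 0.690) per somatotroph, 0.488 per stem-like and 0.125 per thyrotroph-like cell, yet 0.963 (0.808 to 1.15) per endothelial-like and 1.09 (0.711 to 1.73) per fibroblast-like cell, so dilution cannot be told apart from fewer gonadotrophs. Loss of cells between the main and the looser barcode filter is argued against for gonadotroph-like cells by a gap of −5.50 points under the looser filter, against −5.55. The gap was −4.24 under the stricter filter, and 14.3% and 24.2% of cells stayed unnamed under the looser one. Neither library held barcodes under 500 UMIs, so loss of still shallower cells could not be tested. The piece of tissue taken and its dissociation cannot be told apart from age, since the number of libraries per age was 1, and age itself was not tested.

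CXCL9, CXCL10, CXCL11 and IDO1 transcripts were higher in stem-like and endothelial-like cells of the 6-month library. RNA shared by all cells cannot lift a class above the all-cell CPM, and in endothelial-like cells the median ratio of class to all-cell CPM was 8.30 (macrophage genes 0.0925), with CXCL9 at 11.9, CXCL10 at 11.2 and IDO1 at 5.41, which argues against free RNA from immune cells for these 3 genes, while CXCL11 stood at 1.03. In stem-like cells that median was 0.542 (macrophage genes 0.053, endothelial genes 0.0981). This gap decides nothing, since genes were named only from 0.5 of the all-cell CPM and the compared genes mark other classes. UMIs per cell of CXCL9 were 13.97 times those in the hormone-producing class with most. They were 21.6 times for CXCL10 and 8.48 times for CXCL11 (at least 4.28), against 1.04 to 1.17 times for C1QA, C1QB and C1QC. These UMIs per cell argue against free RNA from any class for the 3 chemokine genes. For IDO1 in stem-like cells, at 2.91 times (1.08 to 11.1), free RNA cannot be told apart from expression because its counts were few. More interferon gamma transcript is a candidate explanation for endothelial-like cells, as IFNG over all cells was 10.2-fold higher at 6 months (6.84 to 15.9). T or NK-like cells held 302 of the 331 IFNG UMIs at 6 months, and within them IFNG was at 51.0 and 74.6 CPM. The all-cell value thus largely restates their larger share (0.721% and 8.14%). An immune response in the 6-month preparation and age both stay open and untested.

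In gonadotroph-like cells of the 6-month library, immediate early genes were lower and cluster 31 combined IGFBP1 with little FSHB. The list median was below 0 in 6 of the 7 classes. Under the main settings endothelial-like cells alone (0.65) argued against handling that acted alike on all classes. With doublets kept their median of 0.23 fell below the limit set for this test, so handling of that kind stays undecided. Handling that acts on some classes only was not tested and stays open. Cluster 31 alone does not account for the lower list, whose median was −0.90 without it. Doublets with lactotrophs are argued against as the origin of cluster 31, where PRL made up 5.04% of UMIs against 7.19% in clusters 11 and 22. A state of the gonadotrophs tied to age may still underlie both features, and with 1 library per age this was not tested.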

How the results depend on the processing

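The alternatives chosen after seeing the data were the 3 other naming rules, gonadotroph-like cells without cluster 31, lactotroph-like cells of cluster 7 alone, shares among hormone-producing cells, and list members without cluster 31, in cluster 7 alone and with free RNA subtracted. No paired analysis was possible because each age had 1 library. The alternatives of a mitochondrial limit of 10% or none were not run, since mitochondrial genes had 0 counts. No thyrotroph-like cluster was named under the looser filter, with doublets kept, at resolutions 0.5 and 2.0, with hormone genes among the variable genes or with genes scaled within each library, so that class has no value there. Unless construction is named, the cause of a change was not tested. Depth limits the corticotroph-like and thyrotroph-like classes most, and counting intervals of ratios do not cover differences between cells or preparations.

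The directions of the gonadotroph-like, somatotroph-like and lactotroph-like shares and of LHB and GH held under every alternative run, while FSHB and PRL changed sign under some. By construction, the smaller denominator of hormone-producing cells gave differences of −17.8 points for gonadotroph-like, −16.3 for somatotroph-like and 37.6 for lactotroph-like cells. The gonadotroph-like difference was −4.24 under the stricter filter. The lactotroph-like difference was 11.04 under the looser filter, 29.1 under the stricter filter, 27.3 at resolution 2.0 and 35.8 under the third naming rule.

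LHB in gonadotroph-like cells (0.36) was 0.41 under the looser and 0.26 under the stricter filter, 0.42 with doublets kept, 0.35 at resolution 2.0, 0.38 with hormone genes among the variable genes, 0.20 on library totals, 0.33 as the mean of per-cell CPM, 0.65 with free RNA subtracted and 0.54 without cluster 31. FSHB (−0.31) was −0.26 under the looser and −0.54 under the stricter filter, −0.18 with doublets kept, −0.47 on library totals, 0.032 as the mean of per-cell CPM, −0.022 with free RNA subtracted and 1.10 without cluster 31.

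GH in somatotroph-like cells (−0.48) was −0.47 under the looser and −0.48 under the stricter filter, −0.50 with doublets kept, −0.46 at resolutions 0.5 and 2.0, −0.58 with hormone genes among the variable genes, −0.46 with genes scaled within each library, −0.25 on library totals, −0.29 on totals without hormone genes, −0.28 as the mean of per-cell CPM and −0.29 with free RNA subtracted. PRL in lactotroph-like cells (−0.20) was 0.038 under the looser filter, −0.21 under the stricter filter and with doublets kept, −0.19 at resolution 0.5, −0.22 at resolution 2.0, −0.20 with hormone genes among the variable genes and by median of ratios, −0.19 with genes scaled within each library and on totals without hormone genes, −0.089 on library totals, −0.061 as the mean of per-cell CPM, −0.15 with free RNA subtracted, 0.16 under the third naming rule and 0.42 in cluster 7 alone.

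Because more or fewer genes were measured, a minimum of 20 counts gave 1441 genes at least 2-fold apart in gonadotroph-like, 443 in somatotroph-like and 779 in lactotroph-like cells, and a minimum of 300 gave 420 and 51 in the first 2 of these. Without cluster 31, gonadotroph-like cells had 397 such genes, and cluster 7 alone had 320. Somatotroph-like cells had 293 as the mean of per-cell CPM and 201 with free RNA subtracted.

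Of the genes named by rank, 174 of 192 stayed at least 2-fold apart in the same direction under the stricter filter, 182 of 184 under the looser filter, 177 of 185 with doublets kept, 185 of 192 on library totals, 191 of 192 with free RNA subtracted and 190 of 192 by median of ratios. Free RNA subtraction moved the value of 74 genes beyond its interval. Reversed genes were UCP2 in corticotroph-like cells (−0.92 under the stricter filter) and, in T or NK-like cells, DQA (−0.87 under the stricter filter, −1.32 with genes scaled within each library), CD74 (−0.89 and −1.06 there) and CENPF (0.80 under the second naming rule and the third).

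List medians are called reversed here only if they lay at percentile 5 or below or 95 or above. Another 52 of the 136 medians, nearer the middle, also changed sign under some alternative, among them hormone genes in gonadotroph-like cells (0.65 with free RNA subtracted) and puberty-associated genes in lactotroph-like cells (−0.65 as the mean of per-cell CPM). Under free RNA subtraction the medians called reversed were hormone genes (0.25) and gonadotroph regulation (0.055) in somatotroph-like cells, granule genes (−0.47) and interferon response (−0.15) in stem-like cells, the unfolded protein response (−0.26) and extracellular matrix (0.11) in endothelial-like cells, hormone genes in macrophage-like cells (2.70) and the cell cycle in T or NK-like cells (0.021). As the mean of per-cell CPM they were oxidative phosphorylation in lactotroph-like cells (0.029), granule genes in stem-like cells (−0.0295), hypophysiotropic receptors in endothelial-like cells (−0.0903), the cell cycle in macrophage-like cells (0.16) and lineage transcription factors in T or NK-like cells (−0.0801). With doublets kept, hypophysiotropic receptors (−0.22) and neuronal excitability (−0.15) reversed in macrophage-like cells, and at resolution 2.0 the same lists did (−0.013 and −0.30). The stricter filter reversed hypophysiotropic receptors in endothelial-like cells (−0.30) and heat shock in T or NK-like cells (−0.21), and the looser filter the cell cycle in macrophage-like cells (0.079). Genes scaled within each library reversed the cell cycle in T or NK-like cells (0.14), as did the second naming rule and the third (0.86). The third naming rule also reversed oxidative phosphorylation in lactotroph-like cells (0.0089), and the first the cell cycle in stem-like cells (−0.0002). Cluster 7 alone reversed oxidative phosphorylation (0.16) and nuclear receptors (−0.056), and leaving out cluster 31 reversed lineage transcription factors in gonadotroph-like cells (0.0056).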

Other observations

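The test of doublets in cluster 33 was chosen before its result was seen, and the tests there of free RNA and of a few cells with TSHB after it. Genes named per cluster here were chosen after their values were seen. Within lactotroph-like clusters, CHGA was lower in the 6-month library in each cluster listed: 1214 and 237 CPM in cluster 8, 828 and 58.2 in cluster 7, 794 and 50.1 in cluster 2, 996 and 54.7 in cluster 5, and 1187 and 80.8 in cluster 21. GAL was at 455 and 285 CPM in cluster 8 (1545 and 50 cells) but at 18.4 and 0.173 CPM in cluster 7 (415 and 1185 cells). In cluster 21, GAL was at 451 CPM in 301 cells and had 0 UMIs in 32 cells, while clusters 2 and 5 had 4.32 and 0.2999 CPM and 2.10 and 1.60 CPM.

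Some unnamed clusters had clear leading genes. Cluster 17 (445 and 91 cells) held CHGA at 6664 and 5716 CPM and the calcium-binding protein gene SCGN at 1029.8 and 1130 CPM. Over all unnamed cells CGA made up 2.40% and 0.434% of UMIs, against 0.140% and 0.0677% in endothelial and immune cells. Any hormone-producing cells in the unnamed clusters are left out of the shares of hormone-producing classes. Cluster 18 (340 and 84 cells) held HES6 at 947 and 857 CPM. Cluster 26, with 19 cells at 3 months and 161 at 6 months, held the dendritic cell genes CLEC9A (328 CPM) and XCR1 (158 CPM) in the 6-month library. Cluster 30 (111 and 49 cells) held the proliferation genes TOP2A (592 and 680.0 CPM) and MKI67 (99.9 and 106 CPM). IFNG was at 51.0 and 74.6 CPM in T or NK-like cells and at 0.206 and 2.10 CPM over all cells.

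Summed over its 83 cells at 3 months, cluster 33 of the somatotroph-like class held TSHB (0.560% of UMIs, against 0.0419% in cluster 6) beside GH, but most of its TSHB UMIs came from cells with little GH. The 5 cells with most TSHB held 92.3% of its TSHB UMIs and had between 0 and 3 UMIs of GH each, while in the other 78 cells GH made up 35.8% of UMIs and TSHB 0.0455%. A few thyrotroph-like cells in the cluster are a candidate explanation. The tests on the cluster as a whole, 83 cells against 0.572 expected doublets of somatotrophs with thyrotrophs and the TSHB share against cluster 6, assumed cells with both transcripts and decide nothing about doublets or free RNA.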
